A study of Mus musculus with 8 samples.

How the data were processed

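RNA from mouse kidney, with the cell type given as IMCD (inner medullary collecting duct), was sequenced in 8 libraries. All 8 carry the label tamoxifen, a drug that switches on some inducible Cre recombinases. 4 libraries have the genotype AVP-flox, in which loxP sites flank the vasopressin gene Avp from its first intron to downstream of its 3' end, and 4 have the genotype AVP-flox;Cre, which adds the recombinase. Per the labels, cDNA was made from 1 ng of total RNA with the SMART-Seq HT kit and 11 PCR cycles, Nextera XT was used for tagmentation, and reads were paired-end of 50 bp. STAR and RSEM are named in the submitters' processing notes, without versions. The genome build and annotation release are not given in the sources used here, so no positions are given. The submitters' series is titled Inducible Avp Knockout Mouse Line.

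The deposited table holds TPM values (transcript abundance scaled to the same total in every library) per Ensembl mouse gene, made by the authors, with 1 column per library and 78298 gene identifiers. Each column sums to 1000000 within 2.04. TPM keeps no record of the number of reads, so the depth of each library is unknown and no counting interval or detection limit is given. The columns named WT were read as AVP-flox and those named KO as AVP-flox;Cre, in the order of their replicate numbers. No column was left out. Genes were matched to symbols in the table itself. 21883 identifiers had no symbol and kept their identifier, and 312 symbols shared by several identifiers were summed, which left 77981 genes. The mouse annotation GENCODE M21, which may not be the release the authors used, supplied transcript sequences for GC content, length and exon number through the gene identifiers, and 86.9% of the tested genes had a match there.

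Analysis used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Values were taken as log2(TPM + 1), genes with a mean of at least 1 TPM over the 8 libraries were tested, and limma with a mean-variance trend compared AVP-flox;Cre with AVP-flox. Tests were two-sided, with Benjamini-Hochberg adjustment over all 19043 genes tested and a threshold of 0.05. Log2 fold changes are AVP-flox;Cre minus AVP-flox, given with their standard error (SE), and folds are ratios of mean TPM. Means are given with the standard deviation (SD) of 4 libraries. Single genes were also compared with an exact permutation test of the difference in mean TPM. 37 gene lists with at least 4 tested members, of which 1 was a check of sex-linked genes, were tested with camera at its preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. Camera compares a list with all other genes, while fry tests whether a list's members move, on balance, one way.

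The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from 6 alternatives added later. The rule named Avp, the genes Aqp2, Aqp3, Aqp4, Slc14a2, Avpr2, Scnn1a, Scnn1b and Scnn1g, the 10 largest rises and the 10 largest falls among changed genes whose groups do not overlap, and up to 4 changed members of each list with the smallest adjusted p. Other genes are named as list members to show what a list held, and this choice was made after their values were seen. The alternatives fixed at that point were a replicate block, pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios and quantile scaling, rescaling without mitochondrially encoded genes and the 10 most abundant genes, limma without the trend or with robust moderation, sample weights, identifiers not summed by symbol, sex as a covariate, a threshold of 0.1, a smallest log2 fold change of 1, and each library left out. The alternatives added after seeing the data were protein-coding genes only, genes whose first 300 nt hold at most 60% GC, genes above 70% GC there, a correction of each library for the trend with that GC content, leaving out AVP-flox 2 with AVP-flox;Cre 2 and 4, and leaving out AVP-flox;Cre 2, 3 and 4. Here the first 300 nt are those of the longest annotated transcript. The values of some named genes are not reported here. Alternatives that need read counts were not run because the table holds none.

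The test was tested on simulated data with 19043 genes in 5 runs, each with 200 changed genes. These were drawn from genes with a mean of at least 5 TPM. The noise was normal, independent between genes and of the same spread in both groups. The test recovered 83.2% of genes given a log2 change of 1 (416 genes) and 96.6% of those given 2 (483 genes). It made 70 false calls over the 5 runs. Recovery of changed genes below 5 TPM, with a spread that differs between groups, or with as many changed genes as were called in the data, was not tested.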

Results

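The data describe mouse kidney samples with the cell type label IMCD, the inner medullary collecting duct, where vasopressin controls the recovery of water from urine. Expression was given as TPM for 4 AVP-flox and 4 AVP-flox;Cre libraries, all from tamoxifen treatment, and the depth behind the values is unknown. The labels do not say whether replicates are separate animals, and if they are not, the p-values measure only the spread between these samples. Pearson correlations of log2 values across genes, which are not independent replicates, ran from 0.956 to 0.975 within groups and from 0.932 to 0.958 between groups. The first principal component held 36.9% of the variance and separated the groups, while the second held 18.3% and was highest in AVP-flox;Cre 2 (57.56) and lowest in AVP-flox;Cre 4 (-42.60). AVP-flox;Cre 2 had 33576 genes above 0 TPM against 50951 to 58232 in the other libraries, and AVP-flox;Cre 4 had 23412 genes of at least 1 TPM against 16608 to 20765 in the others. Xist and Y-linked genes showed the male pattern in 1 AVP-flox library (replicate 1) and 2 AVP-flox;Cre libraries (replicates 1 and 2), and the female pattern in the others. Each group thus includes more than 1 animal, though whether all replicates are separate animals stays unknown.

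Avp itself (ENSMUSG00000037727), the gene flanked by loxP sites, was near 0 in both groups. It was listed at 0 to 0.24 TPM in AVP-flox and at 0 to 0.27 TPM in AVP-flox;Cre, and the groups did not differ by more than their spread (exact permutation test, two-sided p = 0.686). Vasopressin is made in the hypothalamus, so these kidney values cannot show whether the gene was deleted.

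The comparison of AVP-flox;Cre with AVP-flox asked how expression differed between the inducible knockout genotype and its floxed control, and no library carries Cre without floxed Avp. Aqp2 (ENSMUSG00000023013), the water channel that vasopressin regulates in the collecting duct, was 2.54-fold lower in AVP-flox;Cre, at 6304 ± 754 TPM against 15995 ± 1467 TPM (SD, n = 4 per group). Its log2 fold change was -1.35 (SE 0.10, adjusted p = 3.38e-05), it was lower in every AVP-flox;Cre library than in any AVP-flox library, and the exact permutation test gave p = 0.0286, the smallest that 4 against 4 allows. The basolateral water channels Aqp3 and Aqp4 fell as well, with log2 fold changes of -0.63 (SE 0.12, adjusted p = 0.00387) and -0.78 (SE 0.10, adjusted p = 0.000492). Slc14a2, which encodes the urea transporters of the inner medulla, rose from 1013 ± 110 to 1376 ± 70 TPM (log2 fold change 0.45, SE 0.09, adjusted p = 0.00438). Avpr2, the vasopressin receptor of this segment, stood at 482 ± 65 and 506 ± 53 TPM and was not past the threshold (log2 fold change 0.08, 95% interval -0.17 to 0.32, adjusted p = 0.657). The list of water and urea transport held 3 genes that fell, 1 that rose and 2 that did not pass the test, against 3 lower and 2 higher when adjusted over the list alone. As a list it was not past the threshold (adjusted p = 0.516). Its median of -0.28 became 0.05 when values were rescaled without the most abundant genes, Aqp2 among them. That change came mostly from the loss of Aqp2 as a member. With that rescaling Aqp3 moved only from -0.63 to -0.66 and Avpr2 from 0.08 to 0.05. In the list of V2 receptor, cAMP and PKA signalling, Pde1a, a phosphodiesterase, rose 1.65-fold, Prkar2b, a regulatory subunit of protein kinase A, fell 2.04-fold, and 18 of 23 members did not pass the test (list adjusted p = 0.549).

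**Figure D1:**
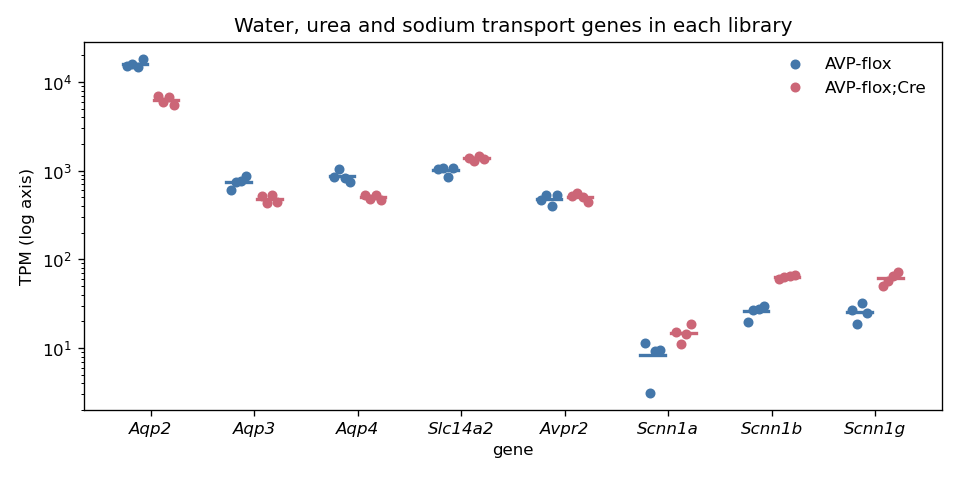
TPM (log axis) of 8 genes in each library, those of water, urea and sodium transport and the vasopressin receptor gene Avpr2, with points for the 4 libraries of each group and lines for group means. Aqp2 lies between 14915 and 18131 TPM in AVP-flox and between 5443 and 7036 TPM in AVP-flox;Cre.

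Scnn1b and Scnn1g, which encode the beta and gamma subunits of the epithelial sodium channel, rose 2.46-fold and 2.38-fold, from 26.0 ± 4.2 to 63.9 ± 3.1 TPM and from 25.6 ± 5.5 to 61.0 ± 8.9 TPM (adjusted p = 8.10e-05 and 0.000527). Scnn1a, the alpha subunit, was at 8.33 ± 3.64 and 14.9 ± 3.1 TPM and did not pass the test (log2 fold change 0.86, adjusted p = 0.0715). It did pass in limma with a replicate block, without AVP-flox 1 and among protein-coding genes. Its lowest adjusted p over 25 alternatives was 0.025. The potassium channel gene Kcnj16 fell from 84.8 ± 12.2 to 18.9 ± 5.1 TPM, and Fxyd2, a modulator of the sodium pump, fell by 0.68 on the log2 scale. Of the 16 tested genes of sodium and potassium transport, 3 rose, 4 fell and 9 did not pass (list adjusted p = 0.950). The median (0.09), mean (-0.10) and test direction (up) of this list differ in sign. In the osmolyte and tonicity list, Nfat5, the transcription factor of the hypertonic response, rose by 0.79, while Slc5a3, the myo-inositol transporter, and Hspa4l, a chaperone, fell by 0.79 and 1.44. That list had 3 higher, 4 lower and 7 not past, with a list adjusted p = 0.549. Among 22 markers of principal and inner medullary collecting duct cells, 5 rose, including Cdh16 (0.82) and Epcam (0.52), and 6 fell (list adjusted p = 0.516).

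Over the transcriptome, 5204 of 19043 tested genes changed (27.3%), with 2491 higher and 2713 lower in AVP-flox;Cre. Of these, 606 were higher and 465 lower by at least 2-fold. The groups did not overlap for 5623 tested genes (29.5%), where chance gives 2.86%. The median log2 fold change was -0.01, and the median SE was 0.16. Esr1, which encodes estrogen receptor alpha, had the largest rise of the named genes, from 1.42 ± 0.57 to 134 ± 66 TPM (log2 fold change 5.67, SE 0.36, adjusted p = 1.57e-05). Gene totals cannot tell the mouse gene from a transgene that holds part of it. The next largest rises were Crisp3 (4.34), Lgi3 (3.99), Spink8 (3.91), Slpi (3.83), Fam89a (3.61), Ifi27l2a (3.59), Fcna (3.42), Igfbp2 (3.40) and Mgp (3.17). Spink8, a serine protease inhibitor family member, reached 4495 ± 414 TPM against 315 ± 112 TPM, and Igfbp2, which binds insulin-like growth factors, reached 1260 ± 36 TPM against 122 ± 35 TPM. The metallothionein genes Mt2 and Mt1 fell by 2.98 and 2.47 on the log2 scale, Mt1 from 584 ± 150 to 102 ± 10 TPM. Igll1 (-2.89), Loxl4 (-2.59), Pex5l (-2.47), Calml3 (-2.46) and Megf11 (-2.27) were also among the 10 largest falls.

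The transcription factor gene Cebpb had the largest fall of the named genes on the log2(TPM + 1) scale (-4.11, SE 0.81, adjusted p = 0.00483). As ratios of mean TPM, Pex5l (13.2-fold) and Igll1 (12.9-fold) fell further than Cebpb (11.1-fold). Cebpb stood at 27.5 to 116 TPM in AVP-flox, 24.95 TPM in AVP-flox;Cre 1 and 0.50 to 1.94 TPM in AVP-flox;Cre 2 to 4. Tmed7 and Alyref were closer to AVP-flox in AVP-flox;Cre 1, at 128 and 69.1 TPM, and stood at 10.7 to 30.4 and 4.34 to 27.7 TPM in AVP-flox;Cre 2 to 4 and at 131 to 151 and 76.9 to 90.9 TPM in AVP-flox. The fall of Tmed7 (-2.22) was not past the threshold without AVP-flox;Cre 2 (adjusted p = 0.0532), and over 25 alternatives its adjusted p ran from 0.000173 to 0.522. The fall of Alyref (-2.22) was not past it without AVP-flox;Cre 2 (adjusted p = 0.0663) or without any 1 of the AVP-flox libraries (0.0511 to 0.0598), with a range of 0.00222 to 0.211. The sizes of these falls depend on single libraries. Without AVP-flox;Cre 1 they were -5.00 for Cebpb, -2.92 for Tmed7 and -2.85 for Alyref. Without AVP-flox;Cre 4 they were -3.85, -1.77 and -1.62. The first 300 nt of Cebpb, Tmed7 and Alyref hold 76%, 77.3% and 72% GC. Of 114 genes with over 80% GC there and an AVP-flox mean of at least 10 TPM, 43.9% were lower and 5.26% higher, against 17.7% and 18.1% of 1234 genes with at most 50% GC. The median deviation of those 114 genes was -0.14 in AVP-flox;Cre 1, -0.55 in AVP-flox;Cre 2, -0.40 in AVP-flox;Cre 3 and -0.64 in AVP-flox;Cre 4. AVP-flox;Cre 2 and 4 stand apart on the second principal component. AVP-flox 2 does not, but it has the lowest share of mitochondrially encoded transcripts. Without AVP-flox 2 and AVP-flox;Cre 2 and 4, Aqp2 stayed past the threshold and 2560 genes passed (1378 higher and 1182 lower). Aqp3 (-0.49, adjusted p = 0.0829) and Cebpb (-3.06, adjusted p = 0.0910) kept their direction with fewer samples but were not past it. Nor were Tmed7 (-1.11, adjusted p = 0.204) and Alyref (-0.94, adjusted p = 0.118), whose falls became smaller. With AVP-flox;Cre 1 as the lone library of its group, assumed to vary like the AVP-flox libraries, 312 genes passed (209 higher and 103 lower) and the calls of 109 of the 144 other named genes ended, as did that of Aqp2 (-1.18, adjusted p = 0.0510, range over 24 alternatives 1.13e-05 to 0.0510). Both of these alternatives were chosen after seeing the data.

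**Figure D2:**
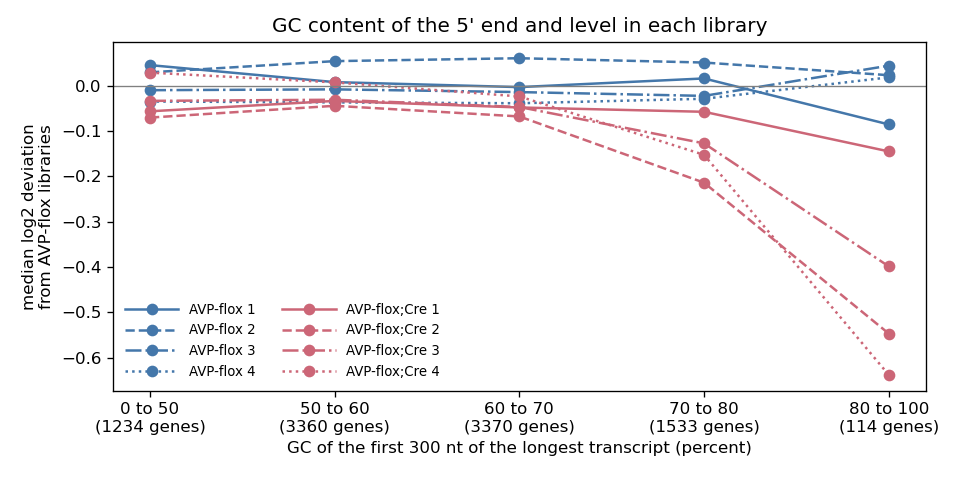
Median log2 deviation of each library from the mean of the AVP-flox libraries (for an AVP-flox library, the other 3), against the GC content (percent) of the first 300 nt of the longest transcript, for genes with an AVP-flox mean of at least 10 TPM. In the bin above 80% GC, AVP-flox;Cre 2, 3 and 4 lie at -0.55, -0.40 and -0.64 and AVP-flox;Cre 1 at -0.14.

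Genes of the interferon response rose together. All 17 tested members were higher, with a median log2 fold change of 1.74 and library medians of 1.41, 2.09, 1.95 and 1.71 in AVP-flox;Cre 1 to 4. Irf7, a transcription factor of the type I interferon response, rose 4.89-fold from 27.4 ± 1.4 to 134 ± 26 TPM. Irf9, a part of the complex that carries the interferon signal, rose 3.30-fold, Ifi44 rose 3.91-fold and Rtp4 rose 4.59-fold. The list had an adjusted p = 1.06e-14 with camera, and an adjusted p = 0.379 with an estimated correlation. Of 14 markers of macrophages and other leukocytes, Csf1r rose (1.10), 13 did not pass the test, and the list median was 0.28 (adjusted p = 0.398). The library medians of these markers were uneven, at 0.71, 0.03, 0.02 and 0.48 in AVP-flox;Cre 1 to 4 and from -0.52 to 0.38 in AVP-flox. In the list of tubular injury, 6 of 13 genes rose, among them the chemokine gene Ccl2 (2.13), Lcn2 (2.18), Clu (1.71) and Vcam1 (1.04), and 7 did not pass (adjusted p = 0.0343 with camera, adjusted p = 0.586 with an estimated correlation). That list was not past the threshold without AVP-flox;Cre 1 (adjusted p = 0.0562), without AVP-flox;Cre 2 (0.0679) or with sex as a covariate (0.0635), and in 10 of 24 alternatives in all (range 0.0123 to 0.190).

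Some genes of matrix, interstitial cells and endothelin signalling rose as well. The cells they came from were not tested. In the extracellular matrix list 10 of 16 genes rose and 6 did not pass, with Mmp2, a matrix protease, up 8.06-fold from 1.07 ± 0.53 to 8.60 ± 2.83 TPM, Sparc up 2.44-fold, and the basement membrane collagens Col4a5 and Col4a2 up 1.61-fold and 1.60-fold. The list had an adjusted p = 4.83e-06, and an adjusted p = 0.338 with an estimated correlation. Of 11 markers of interstitial fibroblasts, pericytes and smooth muscle, 6 rose, including Col1a2 (1.33), Tagln (1.09) and Pdgfra (1.06), and 5 did not pass, Col1a1 among them (-0.08). That list had an adjusted p = 0.00106, and an adjusted p = 0.729 with an estimated correlation. In the endothelin, nitric oxide and purinergic list 6 of 12 genes rose and 6 did not pass, with Entpd1, which breaks down extracellular ATP, at 1.46 and Edn1, the gene of endothelin-1, at 1.09. Its adjusted p = 0.0194, its adjusted p = 0.729 with an estimated correlation, and it was not past the threshold with a filter at 5 TPM (adjusted p = 0.0993, range over 24 alternatives 0.00428 to 0.0993).

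Some markers of intercalated cells and of the papillary surface rose. Intercalated cells, the acid-base cells of the collecting duct, had 7 of 15 markers higher and 8 not past, with the bicarbonate transporter gene Slc4a9 up 3.61-fold, the proton pump subunit gene Atp6v0d2 up 2.25-fold, Rhcg up 2.00-fold and Kit up 1.86-fold (adjusted p = 0.00144, adjusted p = 0.729 with an estimated correlation). Of 10 markers of the papillary surface and urothelium, 7 rose, among them the uroplakin genes Upk3a (5.44-fold), Upk1a (3.31-fold) and Upk3b (2.04-fold) and the surface protein gene Psca (2.35-fold). In that list Trp63, a transcription factor of basal epithelium, fell (-0.80) and 2 did not pass (adjusted p = 0.00144, adjusted p = 0.729 with an estimated correlation). The rise of Upk3a differed between libraries of the male and female patterns by 1.96 on the log2 scale (interaction, adjusted p = 0.0159), with only 1 AVP-flox library of the male pattern, whose spread is taken from the other libraries. Of 16 proximal tubule markers 0 passed the test in limma, 0 had an unadjusted p under 0.05, and their library medians were 1.17 and 1.08 in AVP-flox 1 and 3 and -0.92 and -1.10 in AVP-flox 2 and 4. Genes of aquaporin-2 vesicle trafficking rose in 8 of 15 cases, with Lgals3 up 2.31-fold and the vesicle fusion gene Vamp2 up 1.67-fold, and 7 did not pass (adjusted p = 0.00869, adjusted p = 0.338 with an estimated correlation). That list passed with libraries corrected for 5' GC (median 0.29, adjusted p = 0.0142). At the preset correlation it was not past the threshold only among genes whose first 300 nt hold at most 60% GC, where 9 members are left (median 0.17 against 0.24, adjusted p = 0.216, range over 24 alternatives 7.27e-05 to 0.216).

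Many stress and amino acid response genes fell in AVP-flox;Cre. Of 13 genes of the amino acid response, 9 fell, with Aars1 at 125 ± 2 and 52.6 ± 3.7 TPM (-1.23), the asparagine synthetase gene Asns at 54.7 ± 4.7 and 22.5 ± 1.6 TPM (-1.24) and Chac1, which degrades glutathione, at -2.20. In that list Phgdh, of serine synthesis, rose (0.49) and 3 did not pass (adjusted p = 0.00129, adjusted p = 0.379 with an estimated correlation). The call held with libraries corrected for 5' GC (median -0.68, adjusted p = 0.00239). At the preset correlation it ended only among genes of at most 60% GC, where 6 members are left (median -0.18 against -0.65, adjusted p = 0.190, range over 24 alternatives 6.46e-08 to 0.190). Of 15 heat shock and cytosolic chaperone genes, 9 fell, with Cryab, a small heat shock protein gene, from 13946 ± 1783 to 6346 ± 707 TPM, Hsph1 at -1.36 and Hsp90aa1 at -0.82. Hspa8 rose (0.50) and 5 did not pass (adjusted p = 0.0194, adjusted p = 0.824 with an estimated correlation). This call ended without AVP-flox;Cre 3 (adjusted p = 0.0506) and without AVP-flox;Cre 4 (0.109), in 5 of 24 alternatives in all (range 1.64e-05 to 0.166). In the antioxidant list 7 of 17 genes fell, including Nqo1 (-1.03) and Gstm1 (-0.88), Prdx1 rose (0.46) and 9 did not pass (adjusted p = 0.0495, adjusted p = 0.817 with an estimated correlation). It was not past the threshold without AVP-flox 2 (adjusted p = 0.0819), AVP-flox 3 (0.0550), AVP-flox;Cre 3 (0.0877) or AVP-flox;Cre 4 (0.200), and in 13 of 24 alternatives in all (range 0.000321 to 0.365).

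Some mitochondrial genes fell, by less than 2-fold. Of 34 genes of oxidative phosphorylation, 13 fell and 21 did not pass, with a median of -0.22 (adjusted p = 0.00106, adjusted p = 0.824 with an estimated correlation). Ndufb10 (-0.49), Cyc1 (-0.48) and Atp5f1b (-0.43) were among those that fell. The library median of this list was -0.23 in AVP-flox 2, within the -0.25 to -0.19 of the AVP-flox;Cre libraries, against 0.05 to 0.11 in the other AVP-flox libraries. Of 7 tested mitochondrially encoded genes, 4 fell, led by mt-Nd5 from 993 ± 198 to 601 ± 47 TPM, and 3 did not pass (adjusted p = 0.0194, adjusted p = 0.817 with an estimated correlation). The mitochondrially encoded share was 3.66 ± 0.91% in AVP-flox and 2.68 ± 0.20% in AVP-flox;Cre, and AVP-flox 2, at 2.35%, was lower than all AVP-flox;Cre libraries. The share leaves out 6 of the 13 listed genes, mt-Co2 and mt-Co3 among them, which are given as 0 in all libraries for an unknown reason. That list was not past the threshold with AVP-flox;Cre 1 as the lone library of its group (adjusted p = 0.0892, range over 23 alternatives 2.80e-05 to 0.0892). In the list of fatty acid oxidation and PPAR targets, 6 of 17 genes fell, including Cpt1a (-0.54), which controls fatty acid entry into mitochondria, and Acadvl (-0.48). Acaa2 rose (0.33) and 10 did not pass (adjusted p = 0.0464, adjusted p = 0.729 with an estimated correlation). That call ended without AVP-flox 1 (adjusted p = 0.0745), AVP-flox 3 (0.0824), AVP-flox;Cre 1 (0.112), AVP-flox;Cre 3 (0.0877) or AVP-flox;Cre 4 (0.105), and in 11 of 24 alternatives in all (range 3.95e-05 to 0.331).

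Across the 37 lists, 14 passed with camera at its preset correlation, 8 higher and 6 lower, and 16 passed with fry. Of the 14, oxidative phosphorylation (fry adjusted p = 0.0796) and mitochondrially encoded transcripts (0.0622) did not pass with fry. Water and urea transport (fry adjusted p = 0.0228, lower), endoplasmic reticulum stress (0.0194, lower), endothelial cells (0.0194, higher) and prostaglandin genes (0.0246, higher) passed with fry and not with camera. None of the 14 calls held with an estimated correlation, where 0 lists had an adjusted p and 4 an unadjusted p under 0.05. A larger correlation is not the reason in every list. For aquaporin-2 vesicle trafficking the estimate was 0.0048, below the preset 0.01. Its camera adjusted p still went from 0.00869 to 0.338, and why that call ended was not tested. Adjusted over the list alone, the counts were 5 higher and 4 lower for sodium and potassium transport, 8 and 6 for collecting duct cells, 9 and 0 for intercalated cells, 7 and 0 for interstitial cells, 6 and 1 for tubular injury, and 13 and 0 for extracellular matrix. In the same way they were 2 higher and 9 lower for heat shock, 1 and 7 for fatty acid oxidation, 0 and 14 for oxidative phosphorylation, 2 and 9 for antioxidant genes, 5 and 4 for prostaglandin genes, 3 and 3 for fatty acid synthesis, 0 and 2 for cholesterol synthesis, and 4 and 2 for the thick ascending limb. In the remaining lists apart from water and urea transport they equalled those over all genes.

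**Figure D3:**
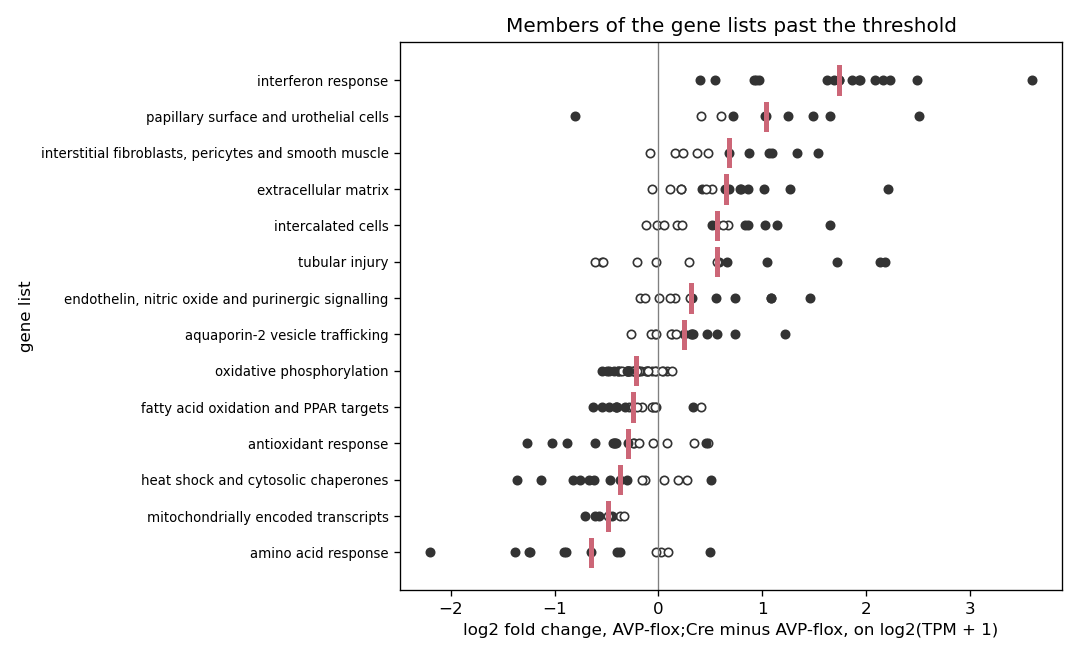
Log2 fold change (AVP-flox;Cre minus AVP-flox) of each tested member of the 14 lists past the threshold, with filled points for genes past it, open points for the others and bars for list medians. The medians run from -0.65 for the amino acid response to 1.74 for the interferon response.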

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

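The tests of whole-transcript GC, of the trend with 5' GC, of the response over genes called without AVP-flox;Cre 1, of a Cre transgene at Esr1, of leukocytes and of Cre itself were chosen only after the result was seen. In all, 27 of 302 groups of 4 libraries held a library far from the others, where chance gives about 1 in 20, or 15.1, and 26 of the 27 are given here.

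Tmed7 stood at 127.9 TPM in AVP-flox;Cre 1 against 10.72 to 30.36 TPM in the other AVP-flox;Cre libraries, and is 1 of 77 genes that were on average at least 1.5 log2 units below the AVP-flox mean in AVP-flox;Cre 2 to 4 and at most 0.7 below it in AVP-flox;Cre 1, 73 of them with every value of AVP-flox;Cre 2 to 4 below those of all other libraries. A smooth trend with GC is too small to be the whole cause. Correcting for whole-transcript GC moved the median drop of 74 genes from -1.85 (quartiles -2.06 and -1.65) to -1.80. Correcting for GC of the first 300 nt moved it to -1.74. After these corrections 100% and 100% of the 74 genes stayed over 1 log2 unit lower. Those shares follow in part from the choice of genes with a fall of at least 1.5 log2 units. They do not bear on a loss that differs between genes of like GC. A response of AVP-flox;Cre 1 that is weaker across genes is argued against. It needs a median shift under 70%, and over 85% was set beforehand as the sign against it. The shift was 92.7% of that of AVP-flox;Cre 2 to 4 over 5138 other changed genes (95% interval 91.7 to 93.8). Those genes were called with this library in the fit, which favors a shift like that of the others. Over other genes called without this library the shift was 86.5% (85.5 to 87.7). Among those that fell it was 86.0%, with an interval of 84.0 to 87.7 that reaches below 85% but not to 70%. The intervals give the spread over genes of a single library, not between libraries. In the 77 genes, which were chosen for a small shift in this library, the shift was 10.3%. A response that is weaker in these genes alone stays open. A loss of transcripts with GC-rich 5' ends in library preparation may contribute, since the first 300 nt of these genes hold 12.8 percentage points more GC than expression-matched genes (73.7% against 60.8%, permutation p = 0.0001, the smallest that 10000 random draws can give), but their whole transcripts are also richer in GC (54.3% against 49.8%, with the same permutation p), and these were 2 of 4 properties compared. What sets the 77 genes apart from others of like GC was not tested and stays open.

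Esr1 was 94.6-fold higher in AVP-flox;Cre. Inducible Cre recombinases are often fused to an estrogen receptor domain, so its reads may come from such a transgene, but the labels do not name the line and the 94.6-fold value is a gene total that does not resolve exons. A rise of the mouse gene with activity on target genes would raise such targets, and 0 of 6 (Pgr, Greb1, Ltf, Muc1, Prlr and C3) passed in limma without a filter, where 1 had an unadjusted p under 0.05 and the lowest adjusted p was 0.256. That count does not decide, because only Muc1 has a mean of at least 5 TPM and tamoxifen acts on the same receptor. The explanations cannot be told apart at the level of gene totals.

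The interferon response genes were higher in AVP-flox;Cre, with a median of 1.74. More leukocytes would raise their markers, whose median was 0.28 (95% interval -0.05 to 0.43), below the interferon median. That interval gives the spread over 14 markers, not between libraries. The markers as a set did not rise as far as the interferon genes. A smaller gain, or a gain of a single leukocyte type, stays open, since Csf1r rose (1.10). Different numbers of male and female mice are argued against because 100% of the genes past the threshold stayed past it with sex as a covariate. The most abundant leukocyte marker, Cd74, stood at 183 ± 88 and 200 ± 69 TPM (SD, n = 4) and did not pass the test. Cre recombinase or the transgene itself may account for the median of 1.74, and it cannot be told apart from loss of Avp because no library has Cre without floxed Avp.

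Upk3a rose more in libraries of the male pattern than of the female pattern by 1.96 on the log2 scale (interaction, adjusted p = 0.0159), but only 1 AVP-flox library has the male pattern, so the other libraries supply the spread of that arm and this difference rests on 1 library. In all, 13 genes passed this test.

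Among transport and epithelial genes, Slc14a2 in AVP-flox 3 stood at 848.4 TPM (others 1054 to 1081), Cdh16 in AVP-flox 1 at 1526 (1908 to 1946), Ppp1r1a in AVP-flox 2 at 94.53 (270.4 to 282.8), Kit in AVP-flox;Cre 2 at 25.73 (32.96 to 34.15) and Vamp2 in AVP-flox 4 at 133.4 (111.6 to 113.4). Among the largest changes, Cebpb in AVP-flox;Cre 1 stood at 24.95 TPM (0.50 to 1.94), Fcna in AVP-flox 4 at 1.44 (2.16 to 2.30) and in AVP-flox;Cre 1 at 19.34 (35.72 to 37.81), Mgp in AVP-flox 3 at 26.07 (12.59 to 14.55) and in AVP-flox;Cre 4 at 259.1 (114.7 to 133.7), and Alyref in AVP-flox 1 at 76.93 (89.32 to 90.93). Among matrix, injury and signalling genes, Col1a2 in AVP-flox;Cre 3 stood at 59.72 TPM (70.19 to 71.42), Tagln in AVP-flox 4 at 22.92 (16.08 to 16.37), Lcn2 in AVP-flox;Cre 2 at 402.4 (194.5 to 218.5), Rtp4 in AVP-flox;Cre 1 at 114.4 (159.9 to 163.1), Ptgds in AVP-flox;Cre 1 at 88.48 (122.4 to 128.8) and Edn1 in AVP-flox;Cre 2 at 4.88 (8.83 to 9.60). Among stress and metabolic genes, Hsp90aa1 in AVP-flox;Cre 2 stood at 189.9 TPM (144.8 to 151.6), Asns in AVP-flox 1 at 47.69 (56.50 to 57.60), Pmvk in AVP-flox;Cre 4 at 47.75 (41.02 to 42.02), Fads1 in AVP-flox;Cre 1 at 36.80 (43.78 to 44.32), Acaa2 in AVP-flox;Cre 2 at 416.6 (350.7 to 356.6), Atp5f1b in AVP-flox;Cre 2 at 2241 (1878 to 1913) and mt-Nd2 in AVP-flox 2 at 1556 (2647 to 2820). AVP-flox 4 had 18211 genes of at least 1 TPM, against 18500 to 18531 in the other AVP-flox libraries.

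Of the 35 splits of the 8 libraries into 4 and 4, 1 (the real one) gave as many as 5204 changed genes, and the highest of the others gave 2. Chance is excluded only at the share of 0.0286 that 35 splits allow, and the other splits mix both groups, which adds the group difference to their spread.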

How the results depend on the processing

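The tests with protein-coding genes, with genes of low or high 5' GC, with a correction for 5' GC and with several libraries left out were chosen only after the result was seen. The count of changed genes (5204) became 3409 with 1643 lower without a filter, where more genes enter the adjustment, and 1071 with 606 higher and 465 lower at a log2 fold change of at least 1. Among genes of at most 60% GC in the first 300 nt it was 2431 (1352 higher, 1079 lower) with 8 lists past the threshold, and above 70% GC it was 937 (287 higher, 650 lower), with fewer genes tested by construction. Without AVP-flox 2 and AVP-flox;Cre 2 and 4 it was 2560 (1378 higher, 1182 lower), and without AVP-flox;Cre 2, 3 and 4 it was 312 (209 higher, 103 lower), with fewer samples by construction. With an estimated correlation 0 lists passed with camera (4 with unadjusted p under 0.05), where 16 passed with fry. Aqp2 stayed negative in 24 alternatives, from -1.40 to -0.89, and was not past the threshold only without AVP-flox;Cre 2, 3 and 4 (-1.18, adjusted p = 0.0510). It has no value when the most abundant genes are left out or among genes of at most 60% GC. Avpr2, not past the threshold, ran from -0.015 without AVP-flox 3 to 0.14 without AVP-flox;Cre 4 when 1 library was left out, and the cause was not tested. Of 145 named genes, 145 kept their call at either pseudocount and 134 without a filter, 125 without AVP-flox 2 and AVP-flox;Cre 2 and 4, and 35 of 144 without AVP-flox;Cre 2, 3 and 4, where the cause beyond sample number was not tested. With replicate numbers as a block, 4431 genes changed, 4257 of them among the 5204. Deviations from the group means correlated at 0.001 to 0.095 for libraries of the same number and at -0.063 to 0.068 for those of different numbers. Such small correlations cannot tell whether the numbers mark pairs. Median-of-ratios, quantile and rescaled values shifted the median of all genes by 0.014, -0.0044 and -0.026. The trend and robust alternatives do not apply to lists, and those that need counts were not run. Depth is unknown, so its limit on low values was not assessed.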

Other observations

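The test of genes below the filter was chosen only after the result was seen. Clock genes moved in both directions in AVP-flox;Cre. Bmal1, the activator of the circadian clock, fell 2.42-fold to 8.68 ± 0.12 TPM (SD, n = 4), while Dbp, Per3 and Nr1d2, which the clock drives, rose 2.67-fold, 1.97-fold and 1.73-fold. Of 16 clock genes, 5 rose, 2 fell and 9 did not pass, and the list was not past the threshold (adjusted p = 0.103). The list test looks for a shift one way, so it says little about genes that move in both directions. Among 13 genes of prostaglandin synthesis and receptors, 4 rose, including Ptgds (1.71) and Hpgd (1.31), which degrades prostaglandins, and 4 fell, including Ptges (-0.52) and Ptger1 (-0.58) (list adjusted p = 0.541). Of 10 endothelial markers, 5 rose, including Tie1 (1.05) and Eng (0.50), and 2 fell, including Emcn from 705 ± 44 to 362 ± 27 TPM (list adjusted p = 0.231). Ddit3 and Hspa5, of endoplasmic reticulum stress, fell by 1.82 and 0.51, with 6 of 19 members lower and 13 not past (list adjusted p = 0.366).

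Of 15 hypoxia genes, 4 rose, including Epas1 (0.61), and 4 fell, including Adm (-1.29) and P4ha2 (-0.79) (list adjusted p = 0.923), and the list's median (0.06) and mean (-0.02) differ in sign. Me1, of fatty acid synthesis, fell from 157 ± 33 to 39.8 ± 14.1 TPM while Fads1 and Fads2 rose (0.79 and 0.74), with 8 of 12 members not past (list adjusted p = 0.596). In glycolysis Pfkl rose (0.41), 3 genes fell, including Hk2 (-0.88), and 11 of 15 did not pass (list adjusted p = 0.516). Among lysosome and autophagy genes 4 rose, including Lamp2 (0.37), 4 fell, including Hexa (-0.66), and 10 did not pass (list adjusted p = 0.923), with a median (-0.03) and mean (-0.07) below 0 and a test direction above it. Of 20 immediate early genes, 3 rose, including Ier3 (1.68), 2 fell and 15 did not pass (list adjusted p = 0.454). Cholesterol synthesis and uptake had 1 higher, 2 lower and 18 not past (list adjusted p = 0.768), and the cell cycle had 2 lower, including Rrm2 (-0.78), and 13 not past (list adjusted p = 0.549). Thin limb markers rose in 3 cases, including Epha7 (0.74), and fell in 2, Cryab and Slc4a11 (-0.66) (list adjusted p = 0.541). Thick ascending limb markers had 4 higher, including Cldn16 (0.69), 1 lower and 4 not past (list adjusted p = 0.535), with a median of 0.27 and a mean of -0.17, and Umod and Slc12a1 did not differ by more than their spread (exact permutation p = 0.143 and 0.114). Wnk4, a kinase gene of the distal convoluted tubule list, fell by 1.06, and the other 5 members did not pass (list adjusted p = 0.923), with a mean of -0.05 and a median of 0.01 that is -0.05 under quantile scaling and -0.01 when rescaled. Of 5 red blood cell genes (list adjusted p = 0.549) and 5 sex-linked genes (list adjusted p = 0.652) 0 passed in limma and 0 had an unadjusted p under 0.05, and the proximal tubule list had an adjusted p of 0.549.

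Below the filter of 1 TPM, 68 genes passed when no filter was set, 40 higher and 28 lower. H19, chosen after its values were seen, was listed at 0.010 to 0.090 TPM in AVP-flox and at 1.29 to 2.22 TPM in AVP-flox;Cre. The genes mt-Co3 and mt-Atp6 were listed at 0 in all 8 libraries.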
